A study of Mus musculus with 10 samples.

How the data were processed

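RNA was sequenced from microglia of the brainstem of mice aged 6 weeks. Per the labels, 3 groups were made: 4 libraries of GFP expressing microglia captured by laser microdissection (LCM_GFP, 3 female and 1 male), 3 libraries of GFP expressing microglia obtained by flow sorting (FACS_GFP, 2 female and 1 male) and 3 libraries of wild-type microglia obtained by flow sorting (FACS_WT, 3 male). The labels call each library a biological replicate. Per the labels' protocols, tissue for sorting was dissociated, enriched on a Percoll gradient and sorted, and RNA was taken up with TRIzol. Tissue for laser capture was briefly fixed in paraformaldehyde and frozen for sectioning, and RNA was extracted with proteinase K and acid phenol. The isolation method is therefore confounded with fixation and with RNA extraction. All libraries were amplified with the Ovation RNA-Seq method before Illumina library construction.

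Per the submitters' processing notes, the authors used CASAVA 1.8.2, TopHat2 2.0.4, Bowtie2 2.0.0 and Cufflinks 2.0.2 with the mouse genome build mm9. The notes do not give the order of the steps, the annotation release or the treatment of reads that map to several places. The deposited expression table holds FPKM values (fragments scaled to transcript length and to mapped fragments) for 37447 genes in the 10 libraries, per the file headers. Any further scaling between libraries is not stated. A second deposited table, in the layout of Cuffdiff per the file headers, holds a log2 fold change between groups and the authors' p-value and q-value for each of the 3 pairwise comparisons. It also holds FPKM values per group, which were not used here. Other deposited tables hold parts of this comparison table and were not used here. Of the genes with FPKM per library, 13661 were listed at 0 in every library, among them 33 of the 37 mitochondrial genes. A value of 0 can therefore be a failed estimate, and such genes are described only as listed at 0.

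The files give no read counts. The steps between low values of single-exon genes gave an implied depth, in units of 1e+06 fragments, of 28.9 to 37.1 for the laser-captured libraries, 41.6 to 54.2 for the sorted GFP libraries and 45.4 to 63.2 for the sorted wild-type libraries. Between 62.4% and 75.7% of the low values lay within 0.2 of a whole multiple of the step, so whole fragments were not recovered, no counting intervals were computed, and the depths are estimates. Sums of FPKM per library ranged from 393949 to 632854.

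For each comparison, only its 2 groups entered the fit. Genes with FPKM of at least 1 in at least 3 of the compared libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (a linear model with moderated variances, using a trend with expression and robust estimation, with statmod 1.5.0). Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. A log2 change on this scale understates the change of genes with low FPKM. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

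A set of 25 gene lists with 573 genes was written from general knowledge of brain cell types and cell functions: microglia, perivascular macrophage, oligodendrocyte, oligodendrocyte precursor, neuron, neurotransmitter and receptor, astrocyte, endothelium, pericyte with smooth muscle and fibroblast, ependyma and choroid plexus, blood leukocyte, erythroid, immediate early, heat shock, inflammatory cytokine, interferon response, antigen presentation, disease-associated microglia, lysosome, cytosolic ribosome, nuclear encoded mitochondrial respiration, mitochondrially encoded, cell cycle, neurodegenerative disease and sex. Of the listed genes 3 were matched through an older symbol and 6 (Irf8, Tubb3, Slc18a3, Ahsp, Rpl13 and Cox4i1) were not matched and were not analysed here. Lists other than sex with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, limma's fry, and the number of members called over all genes or adjusted over the list alone. Named genes were chosen by a rule. They are the 8 largest changes in each direction among called genes whose groups did not overlap in FPKM and whose mean FPKM was at least 5 in the higher group, leaving out predicted genes and small RNAs. To these come up to 4 members of each list in order of mean FPKM, members called against the direction of their list where 5 or fewer, Cx3cr1, and the sex list. The exclusion of small RNAs was read as covering symbols in capitals such as SNORA8. Genes named outside this rule are said to be chosen after their values were seen. The groups, tests, lists, naming rule and all alternative settings but the 3 named below were fixed before the data were examined.

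The test was run on simulated data with known answers, built from the libraries' own means and spreads, in 5 runs per comparison with 200 genes changed. For the laser-captured against the sorted GFP libraries, 13403 genes, 0.597% of the genes changed by 1 on the log2 scale were recovered, 21.5% of those changed by 2 and 64.8% of those changed by 4, and 8.28% of calls were false. For the laser-captured against the sorted wild-type libraries, 13415 genes, the shares were 0.896%, 14.9% and 66.1%, with 6.55% of calls false. For the sorted groups, 11814 genes, they were 69.0%, 94.0% and 99.4%, with 7.22% of calls false. When the simulated changes were those seen in the data, 3.66%, 3.77% and 11.7% of calls were false in the 3 comparisons. Those changes were the calls of this same test, so these shares do not check the calls independently. In all simulations noise was drawn independently for each gene, so variation that genes share was not simulated.

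The alternative settings were log2 pseudocounts of 0.1 and 5, no filter on low values, a filter at FPKM of at least 5, median ratio scaling, quantile normalization, rescaling without mitochondrial and ribosomal RNA genes, all 10 libraries in 1 fit, array weights, sex as a covariate, replicate number as a block, a minimum log2 change of 1, an estimated correlation in camera, and leaving out each library in turn. A further 3 alternatives were chosen after seeing the data: the laser-captured libraries 2 and 4 only, variances estimated separately in each group with limma's moderation, and variances estimated per gene and group without moderation. The replicate numbers were checked for pairing by correlating residuals of libraries with the same number, which gave −0.0333 to 0.0104 for laser-captured with sorted libraries and −0.037 to 0.107 between the sorted groups, so libraries were not treated as pairs. All wild-type libraries were labelled male. Against them, a fit with sex as a covariate therefore takes the group change from the 1 male library of the GFP group alone. No sorted library has replicate number 4. Under the replicate block the laser-captured library 4 therefore does not enter the change, as when it is left out. Gene positions are those of the files in mm9, with starts counted from 1.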

Results

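Microglia, the resident immune cells of the central nervous system, were taken from mouse brainstem by 2 methods and their RNA was sequenced. The 10 libraries formed 3 groups: GFP expressing microglia captured by laser from sections (LCM_GFP, n = 4), GFP expressing microglia sorted from dissociated tissue (FACS_GFP, n = 3) and wild-type microglia sorted in the same way (FACS_WT, n = 3). Values are FPKM as the authors deposited them, and log2 changes are on the log2(FPKM + 1) scale. Between 11075 and 12500 genes had FPKM of at least 1 in the laser-captured libraries, and between 11706 and 11821 in the sorted libraries. The 10 most abundant genes took 7.04% to 34.4% of the FPKM of a laser-captured library and 6.67% to 16.7% of that of a sorted library. Across genes, which are not independent replicates, Pearson correlations were 0.955 to 0.978 between sorted libraries, 0.622 to 0.739 between laser-captured libraries and 0.434 to 0.551 between the methods. The median SD of a gene on the log2 scale was 0.964 in the laser-captured group against 0.130 and 0.170 in the sorted groups. The libraries labelled male had Ddx3y, a Y chromosome gene, at 4.41 to 13.4 FPKM, and those labelled female at 0 to 0.198 FPKM. The laser-captured library 1, labelled female, also had the Y chromosome genes Uty, Kdm5d and Eif2s3y at 15.6, 3.26 and 2.25 FPKM, and the laser-captured library 3, labelled female, had Kdm5d at 5.96 FPKM. The sorted GFP library 2, labelled male, had Xist, an RNA of the inactive X chromosome, at 3.91 FPKM. Mixed libraries or wrong labels were not excluded, which bears on every fit with sex as a covariate.

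The laser-captured and sorted GFP libraries show how the isolation methods differ within GFP expressing mice, which is the question in the series' design. Transcripts of oligodendrocytes and neurons were far higher in the laser-captured libraries. Mbp, myelin basic protein (ENSMUSG00000041607, chromosome 18, 82644538 to 82755029), stood at 1765 ± 494 FPKM (n = 4) against 2.53 ± 0.444 (n = 3), a log2 change of 8.93 (limma adjusted p = 7.19e-06). Snap25, a protein of synaptic vesicle fusion (ENSMUSG00000027273, chromosome 2, 136539189 to 136608164), stood at 848 ± 343 FPKM (n = 4) against 3.25 ± 3.05 (n = 3), a log2 change of 7.75 (limma adjusted p = 0.000152). All 4 laser-captured libraries lay above all 3 sorted libraries for these 2 genes, and none of the alternatives run ended the call of either.

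Of the 38 oligodendrocyte genes tested, 34 rose and 1 fell, with a mean log2 change of 5.02. Adjusted over the list alone, 36 rose and 1 fell. The gene that fell was Evi2a, a membrane protein, with a log2 change of −2.52, and its call ended under median ratio scaling. Apod, a lipid-binding lipoprotein, rose to 541 ± 144 FPKM (n = 4) from 0.193 ± 0.139 (n = 3), while Trf, transferrin, stood at 436 ± 195 against 219 ± 16.9 and did not pass the test. Of the 39 neuron genes tested, 37 rose and none fell, with a mean log2 change of 4.90, and 39 rose adjusted over the list alone. Among them was Mtap2, a microtubule-associated protein of neurons, at 342 ± 133 FPKM (n = 4) against 0.332 ± 0.115 (n = 3). Of the 17 tested neurotransmitter and receptor genes, 15 rose (17 adjusted over the list alone), with a mean log2 change of 4.05. The other members of the 25 matched missed the filter. A gene near 0 in the sorted libraries could pass it only through the laser-captured ones, which favours a rise among the genes tested. By limma's camera these 3 lists were higher (adjusted p = 2.36e-28, 1.04e-30 and 6.71e-13), but none held with an estimated correlation (adjusted p = 0.0842, 0.0712 and 0.0712 with an estimated correlation).

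Genes of several other brain cell types moved the same way. Of the 24 tested astrocyte genes, 19 rose (22 adjusted over the list alone), with a mean log2 change of 4.40. Aldoc, an aldolase of astrocytes (ENSMUSG00000017390, chromosome 11, 78136470 to 78141283), stood at 280 ± 98.6 FPKM (n = 4) against 0.338 ± 0.229 (n = 3), while Glul, glutamine synthetase, stood at 356 ± 90.3 against 399 ± 18.5 and did not pass the test. Of the 12 tested oligodendrocyte precursor genes 10 rose (10 adjusted over the list alone), with a mean of 2.84. Of the 18 tested endothelial genes 14 rose (15 rose and 1 fell adjusted over the list alone), with a mean of 2.32, and of the 6 tested pericyte, smooth muscle and fibroblast genes 5 rose (6 adjusted over the list alone), with a mean of 3.56. Only these 6 of 15 matched pericyte genes passed the filter. The list's median was 0.0153 FPKM in the sorted GFP libraries. Most members could therefore pass only through the laser-captured libraries, and a rise among those tested was nearly given. Ptprz1, a receptor phosphatase of precursors, stood at 62.4 ± 24.1 FPKM (n = 4) against 0.108 ± 0.109 (n = 3), and Slco1a4, a transporter of brain endothelium, had a log2 change of 5.76. All 4 lists were called higher by limma's camera (adjusted p = 2.4e-18, 5.69e-08, 1.04e-07 and 1.04e-05). With an estimated correlation the call of the oligodendrocyte precursor list was the only one of any list in this comparison that held (adjusted p = 0.0391 with an estimated correlation), and the others were at adjusted p = 0.0712 (astrocyte), 0.0712 (endothelium) and 0.109 (pericyte) with an estimated correlation. The precursor list had a median of 0.0167 FPKM in the sorted GFP libraries. Most of its members too could pass the filter only through the laser-captured libraries, which favours a rise among those tested. Ptgds, a prostaglandin synthase, had the largest rise under the naming rule, at 1026 ± 840 FPKM (n = 4) against 0.171 ± 0.0714 (n = 3), and Tmem47 stood at 156 to 575 FPKM in the 4 laser-captured libraries and was listed at 0 in all 3 sorted GFP libraries.

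**Figure D1:**
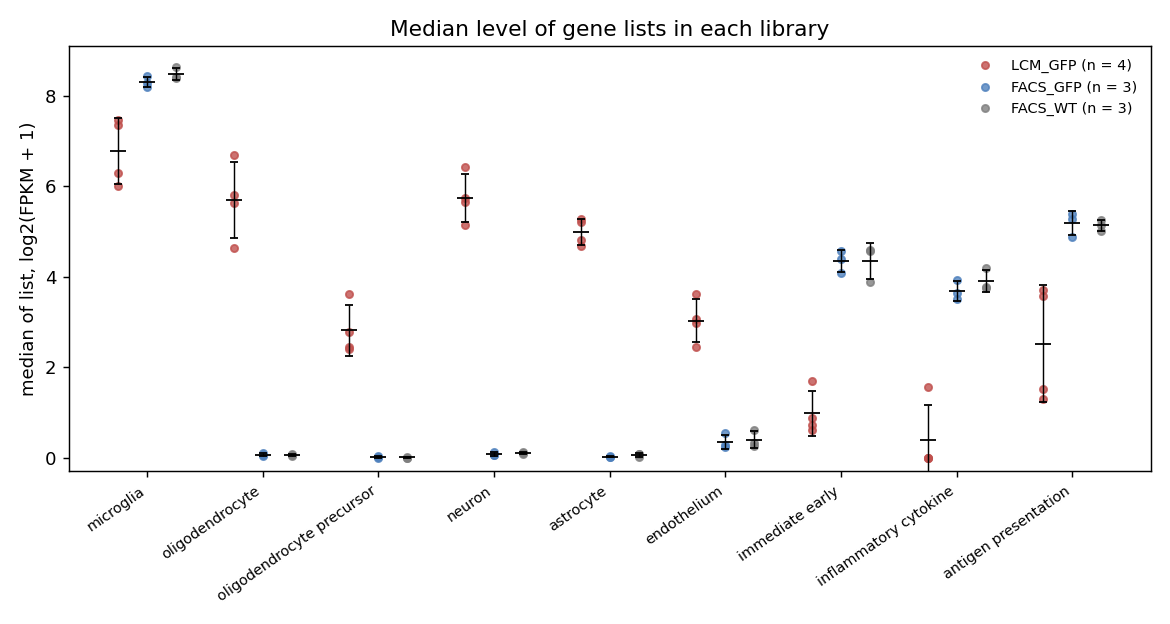
Median log2(FPKM + 1) of 9 gene lists, 1 point per library, coloured by group, with the mean and SD of each group as a bar. In the oligodendrocyte, neuron and astrocyte lists every laser-captured library lies above every sorted library, and in the immediate early list every laser-captured library lies below them.

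Microglial genes were lower in the laser-captured libraries. Of 39 tested microglia genes 25 fell and none rose, with a mean log2 change of −1.68, and 34 fell adjusted over the list alone. Laptm5, a lysosomal membrane protein of blood-lineage cells (ENSMUSG00000028581, chromosome 4, 130469040 to 130492056), stood at 780 ± 425 FPKM (n = 4) against 2308 ± 192 (n = 3). Csf1r, the receptor that microglia need to survive, stood at 447 ± 217 against 894 ± 96.3 and did not pass the test. The microglia list was called lower by limma's camera (adjusted p = 1.04e-05), but not with an estimated correlation (adjusted p = 0.428 with an estimated correlation). The number of members that fell was 6 under median ratio scaling, 14 without a filter on low values, 15 with the replicate block, and 3 without any 1 of the 3 sorted GFP libraries. The call of Laptm5 ended under the first 2 of these settings, without any 1 sorted GFP library and, in a setting chosen after seeing the data, with the laser-captured libraries 2 and 4 only. Among the 10 perivascular macrophage genes tested 3 fell (4 adjusted over the list alone), and camera called the list lower only without a filter, under quantile normalization, with the replicate block or without the sorted GFP library 3.

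Immediate early genes, which cells switch on within minutes of a stimulus, were also lower in the laser-captured libraries, where 19 of 23 tested fell, none rose and the mean log2 change was −3.10, with the same 19 adjusted over the list alone. Fos, a subunit of the transcription factor AP-1 (ENSMUSG00000021250, chromosome 12, 86814840 to 86818223), was listed at 0, 3.63, 0.642 and 6.85 FPKM in the laser-captured libraries 1 to 4 and stood at 158 ± 34.3 (n = 3) in the sorted GFP libraries (limma adjusted p = 0.000953). Jun, its partner in AP-1, stood at 27.7 ± 21.8 FPKM (n = 4) against 770 ± 120 (n = 3), and Zfp36, an mRNA decay factor, at 28.0 ± 14.5 against 348 ± 66.6. Of 16 inflammatory cytokine genes 11 fell (11 adjusted over the list alone), with a mean of −2.97, among them Ccl3, a chemokine, which was at 11.6 FPKM in the laser-captured library 2, listed at 0 in the other 3 and at 84.8 ± 19.1 (n = 3) in the sorted GFP libraries. Of 16 antigen presentation genes 10 fell (12 adjusted over the list alone), with a mean of −2.94, and B2m, the shared chain of class I molecules, stood at 440 ± 157 FPKM (n = 4) against 1597 ± 138 (n = 3). Of 18 interferon response genes 7 fell (8 adjusted over the list alone), with a mean of −1.70, and of 28 lysosome genes 9 fell (17 adjusted over the list alone), with a mean of −1.63. These 5 lists were called lower by limma's camera (adjusted p = 6.94e-08, 3.98e-05, 0.000313, 0.00473 and 0.00198), and none held with an estimated correlation (adjusted p = 0.0842, 0.114, 0.107, 0.211 and 0.426 with an estimated correlation). The call of the interferon response list also ended without the laser-captured library 1 (adjusted p = 0.0513) and with the laser-captured libraries 2 and 4 only (adjusted p = 0.278), a setting chosen after seeing the data. The means of the interferon response and lysosome lists were near that of the microglia list (−1.68). This likeness depends on the pseudocount of 1 for the interferon response list, whose median was 1.19 FPKM in the laser-captured and 6.70 in the sorted GFP libraries. The microglia list had medians of 119 and 308. With a pseudocount of 0.1 the microglia mean was −1.71, while that of the interferon response list was further below 0. Whether any of these 5 lists fell beyond the microglia genes was not tested. Among the largest falls was Hist1h1d, a linker histone, at 0.0308 to 5.42 FPKM in the laser-captured libraries against 134 ± 14.2 (n = 3).

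Other lists moved less or in both directions. Of 37 tested genes of nuclear encoded mitochondrial respiration 9 rose and 1 fell, the same numbers adjusted over the list alone. Atp5b, an ATP synthase subunit, stood at 1227 ± 168 FPKM (n = 4) against 333 ± 25.1 (n = 3), and Ndufa9, a complex I subunit, fell to 13.7 ± 6.40 from 80.9 ± 10.4. The respiration list was called higher by limma's camera (adjusted p = 0.000151), but not with an estimated correlation (adjusted p = 0.211 with an estimated correlation). Of 14 heat shock genes 3 rose and 3 fell (the same numbers adjusted over the list alone). Hsph1, a large chaperone, stood at 91.9 ± 23.4 FPKM (n = 4) against 14.7 ± 0.837 (n = 3), and Hspa5, a chaperone of the endoplasmic reticulum, at 72.8 ± 22.6 against 271 ± 38.3. The mean log2 change of this list was −0.26 while camera's direction was higher (adjusted p = 0.896), and its mean was 0.36 under median ratio scaling. Of 17 disease-associated microglia genes 1 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.44), and the 1 that rose was Spp1, a secreted phosphoprotein, at 21.7 ± 11.4 FPKM (n = 4) against 2.78 ± 0.531 (n = 3). Of 30 neurodegenerative disease genes 6 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.184), with a mean log2 change of 0.18 and a median of −0.34. Sod1, a superoxide dismutase mutated in motor neuron disease, stood at 451 ± 98.5 FPKM (n = 4) against 230 ± 63.4 (n = 3). Its call ended under 12 alternatives, among them the loss of any 1 sorted GFP library or of the laser-captured library 3 or 4. Bin1, an endocytic adaptor, fell to 50.3 ± 11.3 from 176 ± 19.5, a call that ended without the sorted GFP library 1. None of 46 cytosolic ribosome genes passed limma's test, and the list's mean log2 change of −0.03 turned to 0.52 under median ratio scaling, where camera called it higher (adjusted p = 0.0281). None of 17 cell cycle genes passed limma's test. Mki67, a marker of dividing cells, stood at 202, 12.4, 46.6 and 0.0785 FPKM in the laser-captured libraries 1 to 4 against 3.17 ± 1.21 (n = 3). The median log2(FPKM + 1) of the list was 4.61, 0.83, 3.55 and 0.36 in these 4 libraries, and libraries 1 and 3 were also those with the embryonic globin Hbb-y (902 and 439 FPKM). The list's mean of 0.84 turned to −0.10 without the laser-captured library 1. Camera called this list higher with a pseudocount of 5, after rescaling, with the replicate block and without the laser-captured library 2 or 4, and the cytosolic ribosome list higher without the laser-captured library 2 or 4. It called the neurodegenerative disease list higher with the laser-captured libraries 2 and 4 only (adjusted p = 0.0495). Of the lists with fewer than 5 tested members, ependyma and choroid plexus had 1 gene higher (Foxj1) and 1 lower (Kcnj13) of 3 tested, blood leukocyte 1 lower (Cd79b) of 2, and erythroid, sex and mitochondrially encoded none of 4, 4 and 3. The call of Cd79b ended under 13 alternatives, among them the loss of any 1 sorted GFP library or of the laser-captured library 1, 3 or 4.

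With limma, 1681 genes were higher and 2624 lower in the laser-captured than in the sorted GFP libraries, together 32.1% of 13403 tested, and 6022 had an unadjusted p under 0.05. The groups did not overlap in 48.2% of genes, against 5.71% by chance. The median log2 change of all genes was −0.60 as deposited, −0.13 under median ratio scaling and −0.30 under quantile normalization. The share of called genes that were higher was 39.0% as deposited, 59.7% under median ratio scaling (1856 higher, 1252 lower) and 51.6% under quantile normalization, so the excess of lower genes rests on the scaling. The counts depend on how the spread is estimated. Without the sorted GFP library 1, 2 or 3 they were 746, 758 and 738 higher and 312, 329 and 304 lower, and with variances estimated per gene and group they were 957 higher and 1388 lower. With spreads estimated separately in each group under moderation they rose to 1957 higher and 3298 lower, with 4225 of the 4305 calls kept. With the laser-captured libraries 2 and 4 only they were 901 higher and 4084 lower, and these last 3 settings were chosen after seeing the data. The calls of Evi2a, Spp1 and Foxj1 ended without any 1 sorted GFP library and that of Ndufa9 without the sorted GFP library 1 or 3. The calls of Jun, Laptm5, Evi2a and Foxj1 ended with variances estimated per gene and group.

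The laser-captured and sorted wild-type libraries differ in isolation method and in GFP expression, and all 3 wild-type mice were male. Oligodendrocyte, neuronal and astrocyte genes were again higher in the laser-captured libraries. Cdr1, a cerebellar degeneration-related transcript (ENSMUSG00000090546, chromosome X, 58436421 to 58438733), stood at 2116 ± 370 FPKM (n = 4) against 2.11 ± 1.61 (n = 3), a log2 change of 9.51 (limma adjusted p = 1.63e-05). Of the oligodendrocyte genes 34 rose and 1 fell of 38 (35 and 1 adjusted over the list alone), of the neuron genes 38 of 39 rose (39), of the neurotransmitter and receptor genes 15 of 17 rose (17), and of the astrocyte genes 19 of 24 rose (22), where the count in parentheses is adjusted over the list alone. Of the oligodendrocyte precursor genes 10 of 12 rose, of the endothelial genes 13 of 18, and of the pericyte, smooth muscle and fibroblast genes 5 of 6. The limit set by the filter holds here too for the neurotransmitter and receptor, the oligodendrocyte precursor and the pericyte genes. Limma's camera called these 7 lists higher, and the oligodendrocyte precursor list alone held with an estimated correlation (adjusted p = 0.0376 with an estimated correlation). The other 6 were at adjusted p of 0.0722 to 0.105 with an estimated correlation.

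Microglia genes fell in 32 of 39 cases in this comparison (34 adjusted over the list alone), with a mean log2 change of −1.86. The number that fell was 7, 9 and 5 without the wild-type library 1, 2 or 3, and 20 without the laser-captured library 4. It was also 20 with the replicate block, which takes that library out of the change as well. It was 17 without a filter, 11 under median ratio scaling and 1 with sex as a covariate. In the last of these the change is that of the laser-captured library 2 alone against the wild-type libraries, with a mean of −1.13. Cst3, cystatin C, stood at 1113 ± 407 FPKM (n = 4) against 2797 ± 1147 (n = 3), and Cx3cr1, the fractalkine receptor of microglia, at 40.2 ± 19.3 against 136 ± 11.7. The call of Cst3 ended under 11 alternatives and that of Cx3cr1 under 6. Median ratio scaling, sex as a covariate and the loss of any 1 wild-type library ended both, and the loss of the laser-captured library 4 ended that of Cst3. Immediate early genes fell in 19 of 23 cases (20 adjusted over the list alone), inflammatory cytokine genes in 11 of 16 (15), antigen presentation genes in 9 of 16 (14), interferon response genes in 7 of 18 (7), lysosome genes in 14 of 28 (16) and perivascular macrophage genes in 3 of 10 (3). Limma's camera called all of these lists lower except the last (adjusted p = 0.0633), and none held with an estimated correlation (adjusted p = 0.364 for microglia, and 0.0909 to 0.356 for the other 5, with an estimated correlation). The means of the interferon response and lysosome lists, −1.70 and −1.82, were again near that of the microglia list, with the same limit from the pseudocount for the former. The calls of these lists by limma's camera ended with sex as a covariate (adjusted p = 0.115 and 0.0722). That of the interferon response list also ended without the laser-captured library 1 (adjusted p = 0.0548) and with the laser-captured libraries 2 and 4 only (adjusted p = 0.329). Of the nuclear encoded mitochondrial respiration genes 9 rose and 2 fell of 37 (camera adjusted p = 0.000578, and 0.256 with an estimated correlation). Of the heat shock genes 2 rose and 3 fell of 14, and of the disease-associated microglia genes 1 rose and 6 fell of 18. Of the neurodegenerative disease genes 5 rose and 2 fell of 30, of the cytosolic ribosome genes none rose and 3 fell of 46, and none of the 15 cell cycle genes passed limma's test. None of these 5 lists was called by camera. Alternatives called cell cycle higher (a pseudocount of 5, rescaling, the replicate block, and the loss of the laser-captured library 2 or 4) and disease-associated microglia lower (the loss of the laser-captured library 2). The perivascular macrophage list was called lower under quantile normalization, with the replicate block, and without the wild-type library 1 or 3 or the laser-captured library 4.

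Of the 5 sex genes Xist was higher and Ddx3y, Eif2s3y and Uty were lower in the laser-captured libraries, of which 3 were labelled female, than in the male wild-type libraries. All 4 calls ended with sex as a covariate and without any 1 wild-type library, that of Eif2s3y also without the laser-captured library 1, 3 or 4 and that of Uty without 3 or 4. Of 3 ependyma and choroid plexus genes Foxj1 was higher and Ttr and Kcnj13 were lower, and the 1 blood leukocyte gene tested, Cd79b, was lower. The calls of Ttr, Kcnj13 and Cd79b ended with sex as a covariate. Those of Foxj1 and Cd79b ended without any 1 wild-type library, that of Ttr without the wild-type library 1 or 3, and that of Cd79b also without the laser-captured library 1, 3 or 4. None of the 4 erythroid and 3 mitochondrially encoded genes passed limma's test.

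Limma's fry in its directional form asks whether a list shifted in 1 direction and not whether it shifted more than other genes. In both laser-capture comparisons it passed every list that camera called at the preset correlation, with adjusted p up to 0.0217 against sorted GFP and up to 0.0393 against sorted wild-type. For microglia its adjusted p was 0.0192 and 0.0135. It also passed perivascular macrophage (0.00284 and 0.00181) and neurodegenerative disease (0.00284 and 0.0184), and disease-associated microglia against sorted wild-type only (0.0473). The form of fry for changes in either direction passed every tested list except cell cycle and cytosolic ribosome in both comparisons. Among them were heat shock (fry adjusted p = 3.43e-06 and 4.53e-05) and disease-associated microglia (0.00104 and 0.000413). The means of lists with low values depend on the pseudocount. Against sorted GFP they were 6.66 and 2.77 for astrocyte, 3.86 and 1.24 for endothelium and −2.89 and −0.86 for interferon response with pseudocounts of 0.1 and 5. In both comparisons changes of more than 1.5 times were also seen for neurotransmitter and receptor, oligodendrocyte precursor and pericyte with either pseudocount, and for neuron and inflammatory cytokine with 5. The pericyte mean was 2.00 and 1.96 without a filter, and the respiration mean 1.14 and 1.04 under median ratio scaling. With the laser-captured libraries 2 and 4 only the endothelium mean was 1.11 and 1.07.

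With limma, 1649 genes were higher and 2558 lower in the laser-captured than in the sorted wild-type libraries, together 31.4% of 13415 tested, and 5945 had an unadjusted p under 0.05. The groups did not overlap in 46.5% of genes, against 5.71% by chance. The median log2 change of all genes was −0.59 as deposited and −0.11 under median ratio scaling, where 1834 genes were higher and 1237 lower (59.7% higher against 39.2% as deposited), and 51.5% were higher under quantile normalization. With sex as a covariate 883 were higher and 877 lower. That fit takes the change from the laser-captured library 2 alone, the 1 labelled male, so the fall in calls does not show an effect of sex. Without the sorted wild-type library 1, 2 or 3 the counts were 763, 776 and 768 higher and 326, 384 and 331 lower. They were 934 higher and 1362 lower with variances estimated per gene and group, 1933 higher and 3259 lower with spreads estimated separately in each group under moderation, and 888 higher and 3798 lower with the laser-captured libraries 2 and 4 only.

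The same genes were largely called in both comparisons, which share the laser-captured libraries. Of 13192 genes tested in both, 1594 were higher in both, where independent lists of these sizes would share 210, and 2252 were lower in both, where they would share 476. Among these were 34 oligodendrocyte, 37 neuron and 19 astrocyte genes higher in both, and 25 microglia and 19 immediate early genes lower in both. In 20 simulations with unchanged groups that shared the laser-captured libraries, and with noise drawn independently for each gene, no gene was called in both. This is chance with no effect and does not show what the shared libraries add among called genes. When the laser-captured libraries were split so that each comparison had its own 2, in 6 splits, 291 to 322 genes were higher in both, against 34.1 to 42.1 for independent lists, and 1637 to 1871 were lower in both, against 998 to 1140. The total of 3846 became 1511 with sex as a covariate, where the change against wild-type rests on the laser-captured library 2 alone. It became 1991 with variances estimated per gene and group, and 1040 to 1158 without any 1 of the 6 sorted libraries. It rose to 4779 with spreads estimated separately in each group under moderation, 4861 without the laser-captured library 1, 5123 with array weights and 5428 with all 10 libraries in 1 fit.

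**Figure D2:**
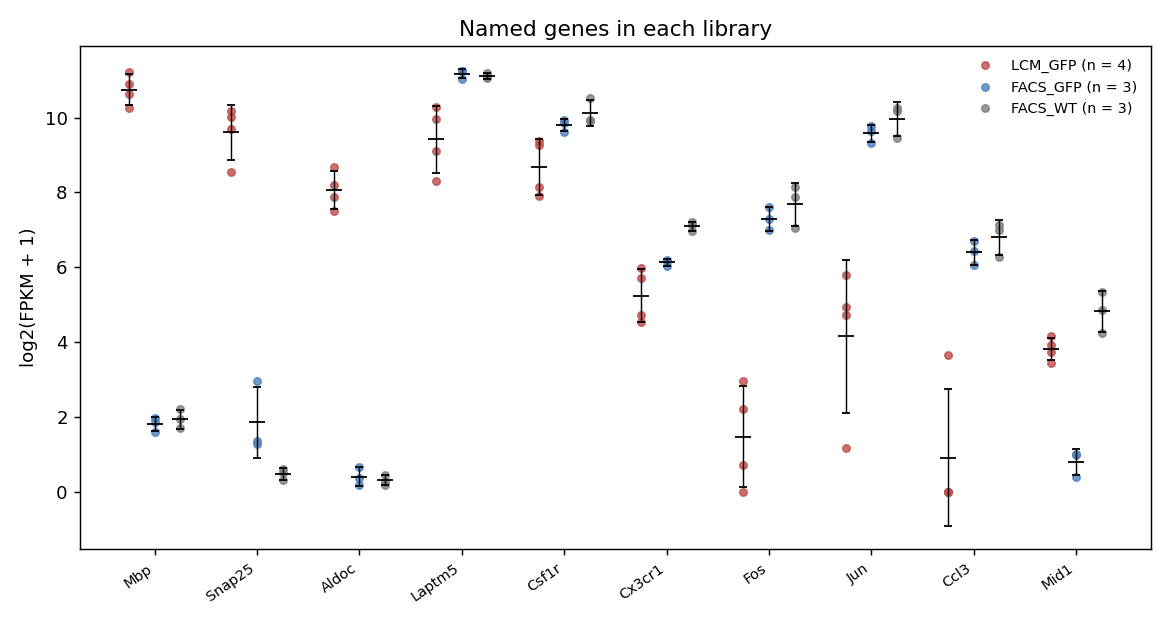
Log2(FPKM + 1) of 10 named genes, 1 point per library, coloured by group, with the mean and SD of each group as a bar. Mbp, Snap25 and Aldoc lie higher in every laser-captured library than in every sorted library, Fos and Jun lie lower, and Cx3cr1 and Mid1 are lower in every sorted GFP library than in every sorted wild-type library.

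The sorted GFP and sorted wild-type libraries show what differed between the kinds of mouse under 1 isolation method. They were close to each other, with 4 genes higher and 9 lower in the GFP libraries. Mid1, a ubiquitin ligase on microtubules (ENSMUSG00000035299, chromosome X, 166123129 to 166443668), stood at 0.764 ± 0.398 FPKM (n = 3) against 28.6 ± 10.8 (n = 3), a log2 change of −4.03 (limma adjusted p = 0.000704), and at 9.85 to 16.8 FPKM in the laser-captured GFP libraries. Slc25a12, an aspartate and glutamate carrier of mitochondria (ENSMUSG00000027010, chromosome 2, 71109120 to 71205806), stood at 63.7 ± 2.25 FPKM (n = 3) against 26.8 ± 1.41 (n = 3), a log2 change of 1.22 (limma adjusted p = 0.002). Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119957811 to 119977400) stood at 69.2 ± 4.10 FPKM (n = 3) against 136 ± 11.7 (n = 3), a log2 change of −0.97 (limma adjusted p = 0.0179), lower in all 3 GFP libraries than in all 3 wild-type libraries.

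Xist was also called, at 7.06 ± 2.76 FPKM (n = 3) in the sorted GFP libraries, of which 2 were labelled female, and listed at 0, 0.00572 and 0.00403 in the wild-type libraries, which were all labelled male. The other 9 called genes fall outside the naming rule or have near copies. Those chosen after their values were seen are the small nucleolar RNA Snora68 and Gm9157, which were higher, and Snord13, SNORA17, SNORA8, Gm11694 and G530011O06Rik, which were lower. G530011O06Rik lies inside Mid1 (chromosome X, 166412975 to 166416849), so reads of the 2 cannot be separated where strand is not stated. The ribosomal pseudogenes Rps19-ps1 and Rps19-ps2 were lower (3.44 ± 0.574 FPKM against 9.47 ± 0.692, and 3.15 ± 0.407 against 9.19 ± 0.548, n = 3 each), and both are uncertain because they share reads with near copies. Snord13 was listed at 0 in the 3 GFP libraries and stood at 427 ± 135 FPKM (n = 3) in the wild-type libraries.

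Outside the sex list, to which Xist belongs, Cx3cr1 was the only list member called, 1 of 39 microglia genes (1 adjusted over the list alone). Laptm5 stood at 2308 ± 192 FPKM (n = 3) against 2214 ± 121 (n = 3), and Jun at 770 ± 120 against 1026 ± 284. No other member of the 16 tested lists passed limma's test over all genes. Adjusted over the list alone, 2 cell cycle and 1 perivascular macrophage gene were higher, and 3 heat shock, 2 oligodendrocyte and 1 interferon response gene lower. Limma's camera called 8 lists lower: cytosolic ribosome, heat shock, lysosome, microglia, disease-associated microglia, oligodendrocyte, inflammatory cytokine and immediate early. The smallest adjusted p of any list was 0.7 with an estimated correlation. With limma's fry it was 0.518 in the directional form and 0.188 in the form for changes in either direction. The mean log2 changes of the 8 lists lay between −0.43 and −0.18, and single libraries moved them by more than 1.5 times. Without the wild-type library 3 the means of cytosolic ribosome, microglia, disease-associated microglia, heat shock and lysosome shrank to −0.13, −0.09, −0.12, −0.28 and −0.10. Without the GFP library 2 those of cytosolic ribosome, immediate early, inflammatory cytokine and microglia shrank, and without the wild-type library 2 that of immediate early shrank to −0.10. The inflammatory cytokine mean grew without the GFP library 3 or the wild-type library 1, and the immediate early mean without the latter. With sex as a covariate the means of cytosolic ribosome, immediate early, inflammatory cytokine and microglia grew to −0.53, −0.50, −0.45 and −0.32. There the change is that of the GFP library 2 alone against the wild-type libraries. Array weights shrank those of heat shock and immediate early, and a pseudocount of 5 or no filter that of oligodendrocyte. The immediate early call also ended without a filter, with array weights, without the sorted GFP library 2 and without the wild-type library 2. The inflammatory cytokine call ended without the wild-type library 2, and the oligodendrocyte call without a filter and with a filter at FPKM of 5. The other 8 lists, antigen presentation, cell cycle, endothelium, interferon response, nuclear encoded mitochondrial respiration, neurodegenerative disease, neuron and perivascular macrophage, were not called (camera adjusted p = 0.0776 to 0.944). Some alternatives did call 3 of them. Cell cycle was higher without a filter, after rescaling, with array weights, and without the sorted GFP library 2 or 3 or the wild-type library 3. Respiration was lower with sex as a covariate (adjusted p = 0.000619), with the replicate block, and without the GFP library 3 or the wild-type library 1 or 2. The perivascular macrophage list was higher without the GFP library 3 (adjusted p = 0.00237). Of the lists with fewer than 5 tested members, no gene of the astrocyte, oligodendrocyte precursor, ependyma and choroid plexus, blood leukocyte, erythroid or mitochondrially encoded lists passed limma's test, and none of the neurotransmitter and receptor or pericyte lists was tested.

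The 13 calls were 0.11% of 11814 genes tested with limma, and 1552 genes had an unadjusted p under 0.05. The groups did not overlap in 20.8% of genes, against 10.0% by chance. The GFP libraries held both sexes and the wild-type libraries only males. With sex as a covariate 7 genes were higher and 5 lower, and the calls of Cx3cr1 and Slc25a12 ended (limma adjusted p = 0.176 and 0.0695). That fit takes the change from the GFP library 2 alone, the 1 labelled male, because all wild-type libraries were male. The log2 change went from −0.97 (SE 0.111) to −1.06 (SE 0.162) for Cx3cr1 and from 1.22 (SE 0.1) to 1.21 (SE 0.154) for Slc25a12. The calls ended as the SE grew, and whether sex adds to these changes was not settled. The call of Cx3cr1 ended without the sorted GFP library 1, 2 or 3 or the wild-type library 1 or 2 (limma adjusted p = 0.0971, 0.0932, 0.0903, 0.0584 and 0.109), as well as without a filter, with all 10 libraries in 1 fit and under a minimum log2 change of 1. Its log2 change stayed between −1.06 and −0.89 under all alternatives. With variances estimated per gene and group no gene was called, and with spreads estimated separately in each group under moderation 28 were higher and 14 lower, both settings chosen after seeing the data. The calls of Xist and the 2 pseudogenes ended without a filter, and theirs and that of Slc25a12 ended with all 10 libraries in 1 fit. The pseudogenes lost their calls with sex as a covariate and without the wild-type library 1 or 2, and Xist without the wild-type library 2. Rps19-ps1 lost its call without any 1 GFP library and Rps19-ps2 without the GFP library 3. The counts were 2 higher and 5 lower without a filter, 0 and 3 with all 10 libraries in 1 fit, 20 and 13 with array weights, 9 and 10 with the replicate block, and 8 and 9 after rescaling without mitochondrial and ribosomal RNA genes. They were 4 and 5 without the GFP library 3, and 5 and 2, 2 and 2, and 10 and 4 without the wild-type library 1, 2 or 3.

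In the authors' deposited table of comparisons, 663 genes were significant and higher and 97 lower in the laser-captured than in the sorted GFP libraries. Of the 598 and 62 of these tested here, limma called 517 and 61 in the same direction. Of the 97 lower genes 62 had the laser-captured group at 0 in that table, and a 0 can be a failed estimate. Most of the 4305 genes limma called were not significant in that table, which held 760. It held 3 of 38 microglia and 6 of 25 immediate early genes as lower, and 21 of 37 oligodendrocyte and 21 of 39 neuron genes as higher. Among genes named above, Mbp, Snap25, Aldoc and Jun were significant there, as was Mki67 (q of 1.647e-08), which limma did not call. Laptm5, Fos and Mtap2 (q of 0.9926, 0.05284 and 0.1558) were not. Against the sorted wild-type libraries the authors' deposited table held 651 higher and 94 lower, and of the 577 and 62 tested here 501 and 62 were called in the same direction. Limma called 4207 genes in that comparison. Among the authors' 94 lower genes, 59 had the laser-captured group at 0. Between the sorted groups the authors' deposited table held 13 higher and 27 lower, and of the 12 and 26 tested here 0 and 2 were called in the same direction. No gene was called in the opposite direction. In the authors' deposited table Cx3cr1 had a q of 1.217e-05 and Mid1 of 9.263e-09 between the sorted groups, while Slc25a12 had a q of 0.856.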

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

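Among 149 values with a test in the laser-captured group of 4 libraries, 16 had 1 library far from the others, with a gap to the nearest library that took more of the whole range than Dixon's 95% critical value. Chance gives this in about 1 in 20 groups of normally spread values, so part of these are due to chance. Where all other libraries are at 0 the gap is the whole range whatever the remaining value is. Ccl3, Ttr, Mpo, Ngp and the inflammatory cytokine median were flagged in this way, and the rate does not hold for them. Ngp and mt-Co3 were also below FPKM of 1 in every laser-captured library. Of the tests in this part, those of embryonic tissue and of dividing cells were set down before their values were seen, and the margin of counting error used with them was chosen only after the result was seen.

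In the laser-captured library 2, Ccl3 was at 11.6 FPKM and listed at 0 in the other 3 (gap 1 of the range), Rarres2 was at 57.7 against at most 0.39 (0.919), Ttr at 8.51 and listed at 0 in the others (1), Stat2 at 25.8 against 9.46 to 10.4 (0.912), and Ddx3y at 4.41 against at most 0.198 (0.893), in the 1 library of the group labelled male. The median log2(FPKM + 1) of the inflammatory cytokine list was 1.56 in that library and 0 in the others (1), and that of the neurodegenerative disease list was 4.74 against 5.04 to 5.09 (0.861). In library 1, Hsp90ab1 was at 751 FPKM against 325 to 349 (0.915), Fth1 at 179 against 349 to 388 (0.863), Ctsa at 79.4 against 367 to 402 (0.943) and mt-Co3 at 0.0416 against 0.317 to 0.365 (0.868). In library 3, Ccr2 was at 2.66 FPKM against 0.101 to 0.335 (0.84), Mpo at 1.17 and listed at 0 in the others (1), and the median of the heat shock list at 5.32 against 5.66 to 5.72 (0.864). In library 4, Ngp was at 0.78 FPKM and listed at 0 in the others (1), and the median of the erythroid list was 0 against 2.29 to 2.75 (0.832).

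The laser-captured libraries 1 and 3 held transcripts of embryonic tissues: the embryonic globins Hbb-y (902 and 439 FPKM), Hbb-bh1 (646 and 626 FPKM) and Hba-x (1850 and 660 FPKM), which were at most 0.102, 0.598 and 2.16 in the other 8 libraries, and Hoxa9 (537 and 26.3 FPKM), Igf2bp1 (87.7 and 25.4 FPKM) and H19 (299 and 49.5 FPKM). Of a separate list of 30 embryonic genes, 12 were at FPKM of at least 1 in library 1, 5 in library 3 and up to 6 in the others (library 4), so the list set library 1 apart but not library 3. By the bound set beforehand the value of 5 counts against embryonic RNA in both libraries, but it lies within counting error of 6, a margin that was added only after the outcome was seen, and the list holds genes such as Igf2bp2 that were at 1.32 FPKM or more in every library, so embryonic RNA and dividing cells cannot be told apart by this list. RNA of embryonic material in both libraries therefore stays open as a candidate source, as do dividing cells, and no biological explanation from the groups of the design was tested, because they give none.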

How the results depend on the processing

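The alternatives with the laser-captured libraries 2 and 4 only and with separate spreads were chosen after seeing the data; the others were planned. The oligodendrocyte, neuron and microglia lists kept direction and call in the first comparison under every alternative run for them except an estimated correlation, the minimum log2 change and separate spreads not being run for lists (adjusted p = 0.0842, 0.0712 and 0.428, with mean log2 changes of 5.02, 4.90 and −1.68 as before); without 1 library their means ranged from 4.81 to 5.38, from 4.70 to 5.19 and from −1.93 to −1.37. Without 1 library, genes higher and lower ranged from 738 to 2034 and from 304 to 3400 (laser-captured against sorted GFP), from 763 to 1990 and from 326 to 3267 (against sorted wild-type), and from 2 to 10 and from 2 to 12 (between the sorted groups), and the overlap from 1040 to 4861. Part of the fall without a sorted library comes from the construction of the test: the median variance of a gene was 0.93 in the laser-captured group and 0.0169 and 0.0289 in the sorted groups, a pooled spread grows when a sorted library leaves, and 3690 or 3691 of the 4305 calls were then still tested. Median ratio scaling gave 1252 and 1237 lower genes in the 2 laser-capture comparisons. With libraries 2 and 4 only, 901 and 4084 genes were higher and lower against sorted GFP, 888 were higher against sorted wild-type, and Ifitm3, which was not called, turned from −0.26 to 1.34 with a call (adjusted p = 0.0249, 0.0249 to 0.971 over its alternatives). Sex as a covariate gave 883 and 877 against sorted wild-type, 7 and 5 between the sorted groups and an overlap of 1511. In both of these comparisons that fit takes the change from 1 male GFP library alone. Separate spreads with moderation gave 1957 higher and 3298 lower against sorted GFP, 4225 of the 4305 calls being shared, and 28 and 14 between the sorted groups. Without moderation they gave 957 and 1388, 934 and 1362, and 0 and 0, with an overlap of 1991; between the sorted groups limma as planned called 13, with 1552 at an unadjusted p under 0.05. Between the sorted groups the counts were 2 and 5 without a filter, 8 higher after rescaling without mitochondrial and ribosomal RNA genes, 0 and 3 with all 10 libraries in 1 fit, 20 higher with array weights, and 9 higher with the replicate block, although the numbers do not pair the libraries. Except where the construction is named, the cause was not tested. Of 3069 values under alternatives of named genes that were called, 2669 kept the call and 400 lost it, and of 3392 values of named genes that were not called, 3126 stayed without one in the same direction, 147 gained one in the same direction, 118 changed sign without a call and 1 turned direction with a call. The depth was implied and not counted, and with the spread of the laser-captured group few genes changed by 1 on the log2 scale were recovered in simulation.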

Other observations

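The tests of scaling, of sex and of the microglial share were chosen only after the results were seen, and the counts of splits of the libraries were planned.

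The laser-captured libraries held more transcripts of oligodendrocytes, neurons, astrocytes, endothelium and pericytes than the sorted libraries, with Snap25 at 374 to 1158 FPKM, while the perivascular macrophage list had a mean log2 change of −1.46 against the sorted GFP and −1.39 against the sorted wild-type libraries, and the ependyma and choroid plexus list had 1 gene higher in both comparisons, with 1 and 2 lower. Scaling is argued against, because the lowest mean log2 change of the oligodendrocyte list over 3 scalings was 4.94. RNA of the surrounding tissue in the captured material, fixation, RNA extraction, loss of transcripts in dissociation and transcripts held by microglia themselves stay open, untested, because each goes with the isolation method. No capture of material without microglia is among these libraries, so they give no background for laser capture.

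Cx3cr1 was at 64.6 to 72.5 FPKM in the sorted GFP libraries and 123 to 146 in the sorted wild-type libraries. A lower share of microglial RNA is argued against, because the median log2 change of the 38 other microglia genes was −0.19 (−0.192, SD 0.205) against −0.97 for Cx3cr1. Sex stays open: the sorted GFP library labelled male was at 64.6 FPKM, below all 3 male wild-type libraries, but it is a single library whose label is in doubt, with Xist at 3.91 FPKM. With sex as a covariate the log2 change went from −0.97 (SE 0.111) to −1.06 (SE 0.162) and the call ended as the SE grew (limma adjusted p = 0.176). That fit takes the change from this same male GFP library alone, so it gives no second check. In all the call ended under 10 of 20 alternatives, with limma adjusted p from 0.00514 to 1. The GFP allele, which the design names through the kind of mouse, may be the source, as an untested hypothesis, since the labels do not say where GFP was inserted.

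Chance in the grouping of libraries is argued against, but not excluded, for the counts of the laser-capture comparisons. There 1 split of 35, the real one, gave as many genes (4305 against at most 769 in the other splits, and 4207 against at most 776). A share of 1 in 35 is the smallest that these splits can give. It was not adjusted over the results tested, which share the laser-captured libraries. Chance is argued against likewise, within the same limit, for the oligodendrocyte list (mean 5.02, highest other 4.40) and the neuron list (4.90, highest other 4.19), each with 1 split of 35. It is not argued against for the microglia list, where 2 of 35 splits gave a mean as large (1.68, highest other 1.69). For the sorted groups the 10 splits are too few for a share under 0.05; the real split, 1 of 10, gave 13 genes and the highest other 9.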
